A study of Mus musculus with 6 samples.

How the data were processed

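RNA of 6 samples of mouse cornea was analysed, 2 in each of the groups unwounded, wounded and wounded with RNase III, with groups and replicate numbers taken from the sample titles. Per the labels' protocols, total RNA was extracted with a column kit and libraries followed standard Illumina steps. The authors deposited 1 table of TPM values for 54446 Ensembl gene rows, and each column has the same sum. STAR, RSEM, DESeq2 and the genome build mm10 are named in the submitters' processing notes, with no role, order or version; the annotation and filters are not given in the sources used here. TPM divides by transcript length and by the library's own total, so a few very abundant transcripts lower all other values of a library, and it keeps no read depth: no counting interval or detection limit can be given. Of the gene identifiers 54409 matched a symbol in the reference table and 37 did not. Coordinates are those of GENCODE mouse release M21 on GRCm38, the assembly that mm10 denotes.

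Values were transformed as log2(TPM + 1), and genes with at least 1 TPM in at least 2 samples were kept, 14748 genes. Fold changes are on that scale, which understates the change of low genes. A group means model with all 6 samples was fitted in limma 3.58.1 under R 4.3.3, with a mean-variance trend in the empirical Bayes step, 3 residual and 3.6 prior degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment per comparison, at adjusted p under 0.05. Gene lists, 28 with 410 members in all, were fixed before the data were examined, and 356 members passed the filter. Of these lists 27 had at least 5 measured members. They were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and again with a correlation estimated from the data. The second form is referred to the 3 residual degrees of freedom, so it can lose a call whatever the correlation. Counts within a list are given over all genes and adjusted over the list alone. The steps were tested on simulated data for the wound comparison with 200 changed genes among 14748 in 10 runs. In these, 7.31% of 2-fold, 66.7% of 4-fold and 94.2% of 8-fold changes were recovered, with 9.4 false calls per run on average. A list of 25 genes shifted by -1 was recovered in 10 of 10 runs. Simulated genes varied independently, so this cannot show how the list test handles members that move together.

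Genes were named by a rule also fixed before the data were examined. It takes Ifnb1, Mmp13 and Tlr3 in every comparison, the 10 largest rises and falls past the threshold whose groups do not overlap (5 each for RNase III against unwounded corneas), and up to 4 members of each list past the threshold, or the 2 most abundant members where fewer than 2 passed. Predicted gene models, pseudogenes and receptor segments were left out of the largest changes. Some genes given by this rule are not reported here. Values by library of Cryaa and S100a8 were added after they were seen. The alternatives were a pseudocount of 0.1, no filter, median-of-ratios scaling, the replicate number as a block, only the 2 groups compared, no trend, and leaving out each library in turn, where a group left with 1 sample is assumed to vary like the others.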

Results

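Gene expression was measured by RNA sequencing in corneas of wild-type C57BL/6 mice aged 6 weeks. The 3 groups were unwounded corneas, wounded corneas, and wounded corneas of eyes that received RNase III by injection under the conjunctiva. RNase III is an enzyme that cuts double-stranded RNA. The wound took away a part of the limbus, corneal epithelium and some stroma. Each group had 2 samples, and nothing in the labels says whether these came from separate animals or from pooled corneas, so the p-values measure the spread between these samples. The table gives TPM, each transcript's share of its library, for 54446 gene rows. TPM keeps no sequencing depth, so the depth is unknown. Between 16751 and 21033 genes were above 0 TPM in a library, the lowest number being that of wounded with RNase III replicate 1. Replicates of a group had Pearson correlations across genes between 0.943 and 0.968, and genes are not independent replicates. The RNase III replicates were the 0.943 pair, and RNase III replicate 2 had 0.954 with wounded replicate 2 and 0.945 with wounded replicate 1. The first principal component, with 59.1% of the variance, had both unwounded libraries on 1 side and the other 4 libraries opposite. Exact permutation of 2 against 2 samples cannot give a two-sided p below 0.333, so tests used limma, which pools the spread over genes.

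The series title names interferon beta and matrix metalloproteinase 13, and the sensor of double-stranded RNA Tlr3 was followed with them. Ifnb1, the interferon beta gene (ENSMUSG00000048806, chromosome 4, 88522025 to 88522774, minus strand, GRCm38), was listed at 0 TPM in all 6 libraries. Mmp13, a collagenase (ENSMUSG00000050578, chromosome 9, 7272514 to 7283331, plus strand), stood at 0.39 and 0.32 TPM in unwounded corneas, 118.3 and 32.46 TPM in wounded corneas, and 27.92 and 33.18 TPM with RNase III. Mmp13 rose with the wound by 5.54 on the log2(TPM + 1) scale (SE 0.55, limma adjusted p = 0.0076), and it was also higher with RNase III than in unwounded corneas, by 4.54 (SE 0.55, adjusted p = 0.0141). Between RNase III and wounded corneas the Mmp13 difference was -1.01 (SE 0.55, adjusted p = 0.494), and without wounded replicate 1 it was -0.09. Without unwounded replicate 1 or 2 the Mmp13 rise with the wound kept its size, at 5.58 or 5.51, though its call was lost. The rise of Mmp13 with RNase III against unwounded corneas was then 4.57 or 4.50, its call also lost. With no library left out and no filter on low values, the limma adjusted p of that rise was 0.0627. Tlr3 (ENSMUSG00000031639, chromosome 8, 45395665 to 45411080, minus strand) had 13.02 and 7.59 TPM in unwounded, 6.91 and 11.06 TPM in wounded and 23.72 and 12.63 TPM in RNase III corneas. The log2 difference of Tlr3 was -0.17 with the wound (SE 0.42, adjusted p = 0.791), 0.91 for RNase III against wounded (SE 0.42, adjusted p = 0.426) and 0.74 for RNase III against unwounded (SE 0.42, adjusted p = 0.248).

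**Figure D1:**
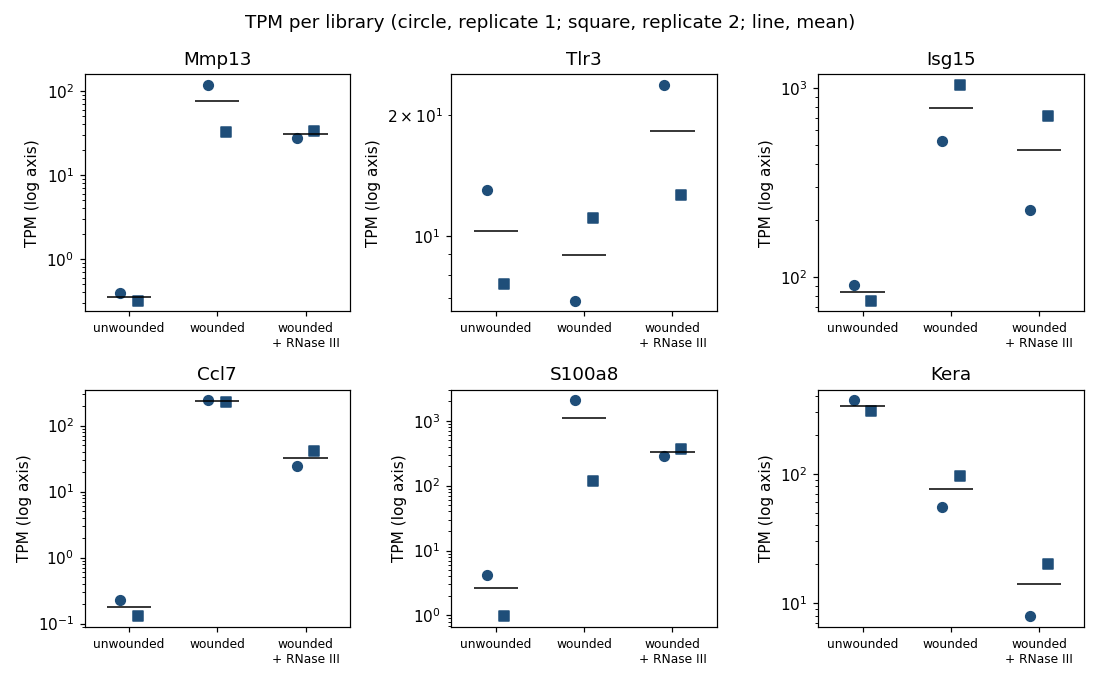
TPM of Mmp13, Tlr3, Isg15, Ccl7, S100a8 and Kera in each library, on log axes whose ranges differ between panels; circles are replicate 1, squares replicate 2 and lines the group mean of 2 libraries. Mmp13 lay at 0.39 and 0.32 TPM in unwounded corneas and between 27.92 and 118.3 TPM in the other 4 libraries.

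The comparison of wounded with unwounded corneas asks how the sampled tissue differed after the injury. TPM are shares of the whole sample and the wound took tissue away, so changed cell mix and changed expression cannot be told apart. Of fixed gene lists, 14 of 24 inflammatory cytokines and chemokines, 7 of 12 neutrophil markers, 21 of 37 interferon-stimulated genes and 9 of 16 wound-edge genes rose. So did 9 of 18 macrophage markers and 6 of 13 matrix metalloproteinases, while 4 of 13 genes of the differentiated corneal epithelium fell. As groups 15 lists passed, and all 15 calls were lost with an estimated correlation (adjusted p between 0.511 and 0.698). The cornified envelope list was among them at an estimated correlation of -0.007, below the preset 0.01. The loss of the cornified envelope call therefore cannot be put down to correlation. The other lists that passed had estimated correlations above the preset, from 0.13 for matrix metalloproteinases to 0.9 for lens. Interferon-stimulated genes had 0.8. For these other lists, correlation and the few residual degrees of freedom of that test cannot be told apart as reasons for the loss. Among 14748 genes tested, 902 were higher and 1450 lower in wounded corneas (limma, adjusted p under 0.05). The largest rises included Ppbp, a platelet chemokine, at 559.3-fold on the TPM + 1 scale, Krt16, a keratin of activated keratinocytes, at 325.9-fold, Il1b at 246.5-fold and Cxcl3 at 234.4-fold. Ccl7 and Ccl2, chemokines that draw monocytes, rose 199.7-fold and 164.2-fold, the neutrophil protein gene S100a8 152.3-fold, the protease inhibitor gene Timp1 143.9-fold and Dynap 122.1-fold. Saa3, an acute-phase gene, was listed at 0 in both unwounded libraries and had 2369.35 and 302.7 TPM after the wound. Wounded replicate 1 also exceeded replicate 2 for Il1b (1008.69 against 164.43 TPM), Timp1 (1993.78 against 481.2 TPM) and Cxcl3 (401.9 against 143.57 TPM). Ccl2 went the other way (234.3 against 436.88 TPM). The largest falls were those of Alox12e, a lipoxygenase, from 81.2 ± 12.5 to 1.58 ± 1.68 TPM (SD, n = 2), Acsm1, Snx31, Plekhs1, Ces1d, Slc13a2, Slc28a3, Ttc36 and Cdo1, by 5.16 to 3.90 on the log2 scale. Spink7 had 43.95 and 14.17 TPM in unwounded corneas and was listed at 0 in wounded corneas.

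Interferon-stimulated genes rose together: 21 of 37 measured members rose and none fell, with a median log2 change of 2.24. The list alone gave 27 rises (adjusted over the list alone), and limma's camera test gave adjusted p = 8.06e-16, or adjusted p = 0.516 with an estimated correlation. Cxcl10 rose from 0.935 ± 0.361 to 34.9 ± 18.1 TPM, Ifit1 from 6.86 ± 0.40 to 139.9 ± 47.6 TPM, Rsad2 from 0.735 ± 0.643 to 19.7 ± 3.0 TPM and Ccl5 from 0.805 ± 1.138 to 36.2 ± 11.9 TPM (SD, n = 2). Sensors of double-stranded RNA went both ways: Zbp1 and Dhx58 rose, by 3.92 and 2.42, while the adaptor gene Mavs fell by 1.56. That list did not pass (2 of 16 rose and 2 fell, the same numbers adjusted over the list alone; camera adjusted p = 0.237). Of 5 measured interferon and receptor genes Ifnar2 rose and Ifnlr1 and Ifngr2 fell, with 2 and 2 adjusted over the list alone (camera adjusted p = 0.542).

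Neutrophil and cytokine genes had the highest list medians. Of 24 inflammatory cytokines and chemokines 14 rose (15 adjusted over the list alone), with a median log2 change of 3.60 (camera adjusted p = 8.06e-16, adjusted p = 0.511 with an estimated correlation). Of 12 neutrophil markers 7 rose (9 adjusted over the list alone), median 4.45 (camera adjusted p = 3.57e-08, adjusted p = 0.513 with an estimated correlation), among them Clec4d at 94.6-fold. Wounded replicate 1 held far more of these transcripts than wounded replicate 2, with S100a8 at 2050.96 against 117.01 TPM. Monocyte and macrophage markers rose in 9 of 18 cases and fell in 1 (11 and 1 adjusted over the list alone), median 1.23 (camera adjusted p = 6.58e-07, adjusted p = 0.513 with an estimated correlation). Ly6c2 rose 71.8-fold and the receptor gene Cd14 49.9-fold. Cd14 had 662.23 TPM in wounded replicate 1 and 112.7 TPM in replicate 2, and Ly6c2 75.48 and 92.75 TPM. Antimicrobial and acute-phase genes included 7 that rose and 1 that fell of 11 (7 and 1 adjusted over the list alone; camera adjusted p = 6.28e-05, adjusted p = 0.513 with an estimated correlation), and Lcn2, an iron-binding defence protein gene, went from 5.92 ± 0.57 to 900.8 ± 977.5 TPM (SD, n = 2).

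Of 13 matrix metalloproteinases 6 rose and 1 fell (6 and 2 adjusted over the list alone), median 1.03 (camera adjusted p = 0.00178, adjusted p = 0.513 with an estimated correlation). Mmp12, a macrophage elastase, rose 53.9-fold, Mmp10 20.2-fold and Mmp3 14.9-fold. Wounded replicate 1 set much of this, with 275.55 TPM of Mmp12 and 2066.02 TPM of Mmp3 against 35.73 and 330.12 TPM in replicate 2. Without it the log2 rises of Mmp12 and Mmp3 were 4.29 and 2.58 and their calls were lost (adjusted p = 0.132 and 0.141). Protease inhibitors and the plasminogen system had 6 of 11 members that rose and 1 that fell (7 and 1 adjusted over the list alone; camera adjusted p = 2.47e-05, adjusted p = 0.516 with an estimated correlation), with Plaur, the urokinase receptor gene, at 47.9-fold and Serpinb2 at 15.3-fold. In the fibrillar matrix list 4 of 25 rose and none fell (5 adjusted over the list alone), namely Tnc, Lox, Tgfb1 and Tgfbi, of which Tnc rose 14.0-fold. The median of that list was -0.10 and its mean 0.37, while camera placed it above other genes (adjusted p = 0.0268, adjusted p = 0.698 with an estimated correlation). Without wounded replicate 1 the fibrillar matrix call was lost (adjusted p = 0.105), as it was without RNase III replicate 1 or 2 (adjusted p = 0.174 and 0.165). It was also lost with only the 2 groups (adjusted p = 0.175) and with median-of-ratios scaling (adjusted p = 0.0584, median 0.17).

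In the epithelium, wound-edge keratinocyte genes rose in 9 of 16 cases (9 rose and 1 fell adjusted over the list alone), median 1.80 (camera adjusted p = 2.2e-08, adjusted p = 0.511 with an estimated correlation). Lamb3, a laminin chain of the basement membrane, rose 9.21-fold and Krt17 15.8-fold. Limbal and basal genes had 4 of 11 members that rose and 1 that fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.0114, adjusted p = 0.519 with an estimated correlation), and the basal keratin gene Krt14 went from 482.1 ± 81.4 to 11605 ± 2312 TPM (SD, n = 2). Cornified envelope genes rose in 5 of 11 cases and fell in 1 (7 and 2 adjusted over the list alone; camera adjusted p = 0.000618, adjusted p = 0.511 with an estimated correlation): Sprr1a rose 54.3-fold and Lce3a fell by 3.56. Differentiated corneal epithelium genes fell in 4 of 13 cases and none rose (the same adjusted over the list alone), median -0.84 (camera adjusted p = 0.0268, adjusted p = 0.663 with an estimated correlation). These were Upk1b, Pax6, Ehf and Klf5, and Pax6, the eye transcription factor, fell by 2.04. The call of this list was lost without unwounded replicate 1 (adjusted p = 0.0598), without a filter on low values (adjusted p = 0.0565) and with scaling (adjusted p = 0.0559). Scaling also ended the limbal and basal call (adjusted p = 0.0556).

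Proliferation genes had higher values in all 24 measured members, 2 of which rose, Mcm3 and Aurka (1 adjusted over the list alone; camera adjusted p = 4.02e-08, adjusted p = 0.6 with an estimated correlation). Immediate early and heat shock genes had 4 of 12 that rose (9 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.000285, adjusted p = 0.608 with an estimated correlation), with Atf3 at 16.0-fold and Egr1 at 5.27-fold. In the lens list Cryba4 and Bfsp1 rose, 2 of 10 members, also when adjusted over the list alone (camera adjusted p = 0.0276, adjusted p = 0.663 with an estimated correlation). The lens call was lost without wounded replicate 2 (adjusted p = 0.251) or with scaling (adjusted p = 0.147). Wounded replicate 2 had 87.88 TPM of Cryaa, a lens crystallin, against 0.71 in replicate 1. Stromal keratocyte markers did not pass (camera adjusted p = 0.059), though 2 of 9 fell, Kera and Ogn (2 adjusted over the list alone). Other lists that did not pass were the conjunctiva (camera adjusted p = 0.545), the corneal endothelium (0.0772), pigment cells and retina (0.0695), skeletal muscle (0.93, with a median of -0.32 and a camera direction of up), nerve (0.545), mast cells (0.258), vessels (0.962, median -0.18 and direction up), red blood cells (0.115) and mitochondrially encoded genes (0.0695). For the conjunctiva list the median was -0.52 and the camera direction up. Of the 15 lymphocyte genes 1 was measurable, so that list was not tested.

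The all-gene median of the wound comparison was -0.258, and median-of-ratios scaling moved it to -0.003; changes can be read relative to that shift. With that scaling 1544 genes were higher and 1007 lower, a share of 60.5% higher in place of 38.4%. The counts of the wound comparison depended on each of 3 libraries: 22 higher and 3 lower without unwounded replicate 1, 22 and 4 without unwounded replicate 2, and 51 and 20 without wounded replicate 1.

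**Figure D2:**
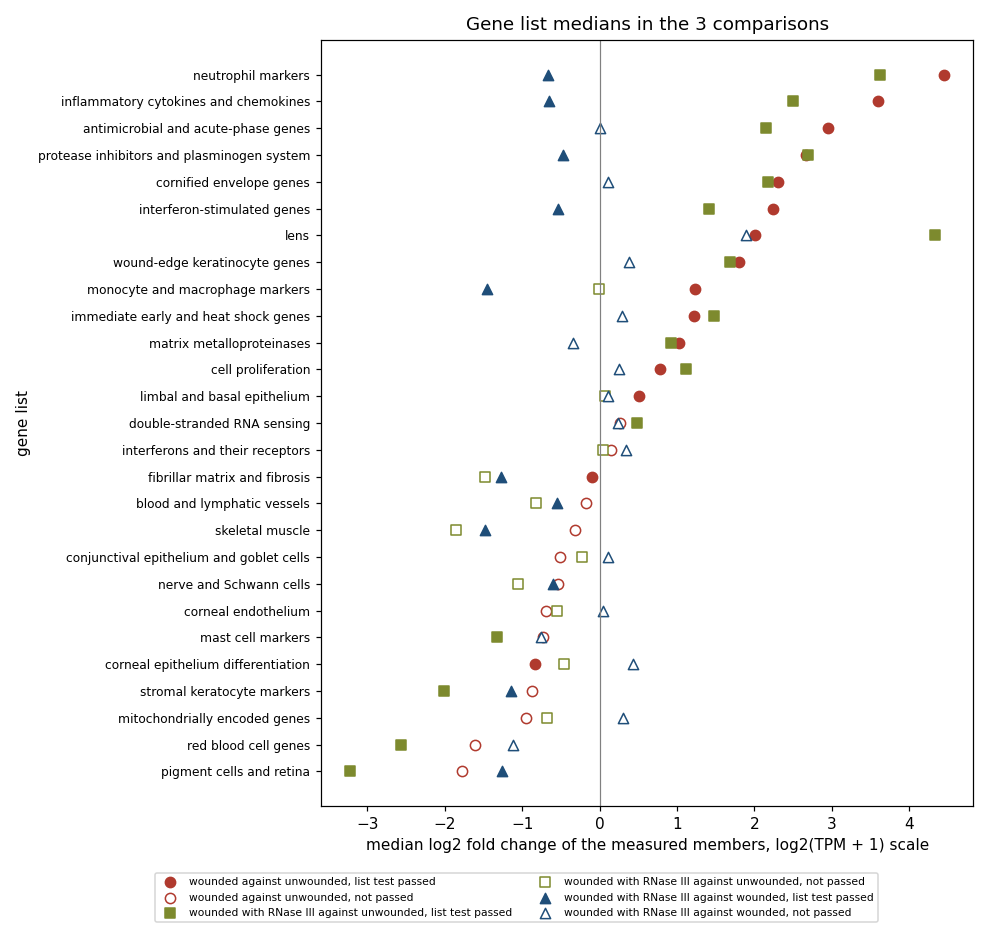
Median log2 fold change of the measured members of 27 gene lists in the 3 comparisons, on the log2(TPM + 1) scale, with filled symbols for lists that passed the camera test at adjusted p under 0.05 and open symbols for those that did not. The keratocyte list had medians of -0.87 after the wound, -2.01 with RNase III against unwounded and -1.14 with RNase III against wounded corneas.

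RNase III against wounded corneas asks how wounded tissue differed after injection of the enzyme. The labels do not say whether the wounded corneas had a control injection, so the injection itself cannot be set apart from the enzyme. No single gene passed, and genes of the stroma and of macrophages had lower values as groups in RNase III corneas, calls that were lost with an estimated correlation (adjusted p = 0.658). Interferon-stimulated genes had a median below wounded corneas in RNase III replicate 1 (-1.35) and not in replicate 2 (0.24). Of 27 lists 11 passed, all downward, and all 11 were lost with an estimated correlation, with adjusted p between 0.658 and 0.722. limma called 0 genes higher and 0 lower among 14748 (smallest adjusted p = 0.124). An unadjusted p under 0.05 was found for 1838 genes, 1154 higher and 684 lower, where 737 are expected by chance. With only the 2 groups compared it was found for 1079 genes, so the size of the excess depended on including the unwounded libraries. The all-gene median was 0.0909, and -0.0123 with median-of-ratios scaling. In the simulated wound comparison of 14748 genes, 7.31% of 2-fold changes and 66.7% of 4-fold changes were recovered. That simulation planted 200 changes in the wound comparison, so these rates need not hold for RNase III against wounded corneas.

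Stromal keratocyte markers had lower values in all 9 members, with a median log2 difference of -1.14 (0 of 9 passed over all genes and 4 fell adjusted over the list alone; camera adjusted p = 2.99e-07, adjusted p = 0.658 with an estimated correlation). Ptgds had 1643.6 ± 651.3 TPM in wounded and 356.16 and 828.96 TPM in RNase III corneas, and the matrix proteoglycan gene Dcn 1447.6 ± 415.7 TPM (SD, n = 2) against 463.76 and 573.02 TPM. The fibrillar matrix list had a median of -1.27, and 8 members fell adjusted over the list alone (camera adjusted p = 6.23e-12, adjusted p = 0.658 with an estimated correlation). Both RNase III libraries lay below both wounded libraries for 17 of 25 members. Chance gives 16.7% for 1 gene, but the members move together (estimated correlation 0.73), so they are not 25 separate results. The most abundant members of the list were Sparc, at -1.39, and Tgfbi, at 0.06. The keratocyte and fibrillar calls held without each of the 6 libraries in turn, but the fibrillar median was -0.64 without RNase III replicate 1 and -2.05 without replicate 2.

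Monocyte and macrophage markers had a median of -1.45, with 14 of 18 members lower in both RNase III libraries than in both wounded libraries (9 fell and 2 rose adjusted over the list alone; camera adjusted p = 2.01e-08, adjusted p = 0.658 with an estimated correlation). Lyz2, a macrophage lysozyme, had 335.9 ± 85.5 TPM (SD, n = 2) in wounded and 134.05 and 165.9 TPM in RNase III corneas, whereas Arg1, arginase, stood at 0.95 (adjusted p = 0.317). Interferon-stimulated genes had lower values in 32 of 37 members, median -0.54 (8 of 37 lower in both RNase III libraries than in both wounded libraries, near the 16.7% of chance; 0 passed and 1 fell adjusted over the list alone; camera adjusted p = 1.66e-05, adjusted p = 0.7 with an estimated correlation). Isg15 had 524.57 and 1042.27 TPM in wounded and 228.09 and 714.9 TPM in RNase III corneas, and Ifi27l2a 517.2 and 823.34 TPM against 45.4 and 141.24 TPM. Without RNase III replicate 1 the median of the interferon list was 0.24 and its call was lost (adjusted p = 0.589).

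Inflammatory cytokines and chemokines had a median of -0.66 (3 of 24 fell adjusted over the list alone; camera adjusted p = 0.00025, adjusted p = 0.658 with an estimated correlation), with Il1b at -1.76 and Cxcl3 at -0.14. Neutrophil markers had a median of -0.67 (0 of 12 adjusted over the list alone; camera adjusted p = 0.0436, adjusted p = 0.722 with an estimated correlation), with S100a9 at -0.57 and S100a8 at -0.60. Both rested on wounded replicate 1: without it the cytokine median was -0.03 (adjusted p = 0.892) and the neutrophil median 1.01, upward (adjusted p = 0.00321). Without RNase III replicate 2 both calls were lost too, though the medians were still -0.544 for cytokines and -0.795 for neutrophil markers. The neutrophil call was also lost without RNase III replicate 1 (adjusted p = 0.0548), with a pseudocount of 0.1 (adjusted p = 0.0731) and with scaling (adjusted p = 0.118). Protease inhibitors and the plasminogen system had a median of -0.48, with Timp1 at -1.59 and A2m at -0.92. Of 11 members 1 fell adjusted over the list alone (camera adjusted p = 0.000514, adjusted p = 0.658 with an estimated correlation). The call was lost without wounded replicate 1, where the median was still -0.43.

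Pigment cell and retina genes had lower values in all 11 members, median -1.26 (-0.36 without RNase III replicate 1), with Dct at -1.26 (0 adjusted over the list alone; camera adjusted p = 0.00025, adjusted p = 0.658 with an estimated correlation). Vessel genes had a median of -0.55, with Emcn at -1.30 and Vegfa at 0.54 (0 of 12 adjusted over the list alone; camera adjusted p = 0.00739, adjusted p = 0.658 with an estimated correlation), and the call was lost without wounded replicate 1 (adjusted p = 0.155) or RNase III replicate 1 (adjusted p = 0.0509, median -0.14). Nerve genes had a median of -0.61, with the myelin gene Mbp at 0.77 and Gap43 at -0.37 (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0345, adjusted p = 0.658 with an estimated correlation). The nerve call was lost without wounded replicate 1 (adjusted p = 0.206) or RNase III replicate 1 (adjusted p = 0.224, median -0.13), without a filter (adjusted p = 0.0691) and with scaling (adjusted p = 0.0548). Skeletal muscle genes had a median of -1.48, with Tnni2 at -0.17 and Mb at -1.84 (0 of 8 adjusted over the list alone; camera adjusted p = 0.0486, adjusted p = 0.722 with an estimated correlation). The muscle call was lost without wounded replicate 1 (adjusted p = 0.778, median -0.25) or either RNase III library (adjusted p = 0.0616 and 0.322). It was also lost without a filter (adjusted p = 0.0753), with scaling (adjusted p = 0.118) and without a trend (adjusted p = 0.0544).

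The epithelial lists did not pass in this comparison. Their medians were 0.43 for corneal differentiation (camera adjusted p = 0.172), 0.11 for limbal and basal genes (0.894), 0.38 for wound-edge keratinocyte genes (0.0966), 0.11 for cornified envelope genes (0.264) and 0.11 for the conjunctiva (0.793, camera direction down). Matrix metalloproteinases had a median of -0.35 (camera adjusted p = 0.07), sensors of double-stranded RNA 0.24 (0.0983), interferons and receptors 0.35 (0.766), the endothelium 0.05 (0.933, camera direction down), lens 1.89 (0.103), mast cells -0.75 (0.0611), antimicrobial genes 0.00 (0.766, camera direction down), proliferation 0.25 (0.0983), immediate early genes 0.28 (0.612), red blood cells -1.12 (0.0618) and mitochondrially encoded genes 0.30 (0.793).

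Across genes, the wound and RNase III fold changes had a Pearson correlation of -0.325, where unchanged groups that share the wounded libraries gave -0.502 on average in 100 simulations. The covariance was -0.193 against a simulated -0.0798, a difference of -0.113. The simulation gave every group the same spread per gene, so it cannot size what the wounded pair's own spread adds. With 1 wounded library on each side the covariance was 0.0465 or -0.223, so its sign depended on which library stood where. Of the 902 genes that rose with the wound, 64.5% had lower mean log2 values with RNase III than in wounded corneas. Of the 1450 that fell, 84.6% had higher ones. These shares use the wounded libraries on both sides and so lie above chance with no effect at all.

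RNase III against unwounded corneas asks which parts of the wound response were present under the enzyme. Of the fixed lists, 13 of 24 cytokines and chemokines, 9 of 16 wound-edge genes, 6 of 24 proliferation genes and 5 of 12 neutrophil markers rose, and 6 of 9 keratocyte genes fell. As groups 16 lists passed, and all 16 calls were lost with an estimated correlation (adjusted p between 0.459 and 0.525). 696 genes were higher and 675 lower among 14748 (limma, adjusted p under 0.05). Ppbp rose 494.4-fold, Krt16 267.3-fold, Cxcl3 212.5-fold and Dynap 125.1-fold, and Saa3, listed at 0 in unwounded corneas, had 289.6 and 601.81 TPM. Kera, the gene of the corneal proteoglycan keratocan, fell from 335.3 ± 44.7 to 14.0 ± 8.5 TPM (SD, n = 2), Clec3b by 4.31 and Ttc36 by 4.48 on the log2 scale. Spink7 was listed at 0 in both RNase III libraries, as was the histone gene Hist2h2aa2, which has near-identical copies in the genome and is uncertain for that reason.

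Keratocyte markers fell in 6 of 9 cases (9 adjusted over the list alone), median -2.01 (camera adjusted p = 1.94e-05, adjusted p = 0.49 with an estimated correlation), with Lum 6.04-fold and Ptgds 5.12-fold lower. Interferon-stimulated genes rose in 9 of 37 cases (19 adjusted over the list alone), median 1.42 (camera adjusted p = 8.21e-10, adjusted p = 0.49 with an estimated correlation), with Oas1a at 7.12-fold and Usp18 at 7.07-fold. Cytokines and chemokines rose in 13 of 24 (15 adjusted over the list alone; camera adjusted p = 4.36e-14, adjusted p = 0.49 with an estimated correlation). Neutrophil markers rose in 5 of 12 (10 adjusted over the list alone; camera adjusted p = 1.51e-06, adjusted p = 0.49 with an estimated correlation). Wound-edge genes rose in 9 of 16 (12 adjusted over the list alone; camera adjusted p = 6.59e-10, adjusted p = 0.459 with an estimated correlation), with Lamb3 at 15.2-fold. Cornified envelope genes rose in 6 of 11 (7 rose and 1 fell adjusted over the list alone; camera adjusted p = 8.74e-05, adjusted p = 0.459 with an estimated correlation). Antimicrobial genes rose in 4 of 11 (9 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.21e-05, adjusted p = 0.49 with an estimated correlation). Proliferation genes rose in 6 of 24 (18 adjusted over the list alone; camera adjusted p = 6.59e-10, adjusted p = 0.49 with an estimated correlation), among them Mcm3 at 4.68-fold and Rrm2 at 3.65-fold. Immediate early genes rose in 4 of 12 (9 adjusted over the list alone; camera adjusted p = 4.21e-05, adjusted p = 0.49 with an estimated correlation), with Egr1 at 6.03-fold.

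Matrix metalloproteinases rose in 3 of 13 cases and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.02, adjusted p = 0.49 with an estimated correlation), with Mmp10 at 6.76-fold. Protease inhibitors rose in 5 of 11 and fell in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0157, adjusted p = 0.525 with an estimated correlation), with Timp1 at 47.8-fold and Plaur at 34.5-fold. Of the sensors of double-stranded RNA Zbp1 rose, 1 of 16 (0 adjusted over the list alone; camera adjusted p = 0.02, adjusted p = 0.49 with an estimated correlation). Lens genes rose in 2 of 10 (2 adjusted over the list alone; camera adjusted p = 0.00116, adjusted p = 0.496 with an estimated correlation), namely Cryba4 and Bfsp1, and RNase III replicate 2 had 1281.15 TPM of Cryaa against 1.07 in replicate 1. Pigment and retina genes fell in 1 of 11, Rpe65 (11 adjusted over the list alone; camera adjusted p = 0.00018, adjusted p = 0.49 with an estimated correlation). Red blood cell genes fell in 0 of 5 (5 adjusted over the list alone; camera downward, adjusted p = 0.0125, adjusted p = 0.49 with an estimated correlation), with Hbb-bs at -2.78 and Hba-a2 at -2.51. Mast cell genes fell in 1 of 5, Mcpt4 (4 adjusted over the list alone; camera adjusted p = 0.0249, adjusted p = 0.49 with an estimated correlation). Without RNase III replicate 2 the calls of the sensors and of the metalloproteinases were lost (adjusted p = 0.0655 and 0.082), without RNase III replicate 1 that of the protease inhibitors (adjusted p = 0.0502). The mast cell call was lost without RNase III replicate 1 or unwounded replicate 1 (adjusted p = 0.0815 and 0.0598).

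Fibrillar matrix genes did not pass as a list (camera adjusted p = 0.0559), though 6 of 25 fell and 3 rose (13 fell and 3 rose adjusted over the list alone), with Postn 6.56-fold and Col5a2 5.75-fold lower and Tnc 7.37-fold higher. Monocyte and macrophage markers did not pass either (4 rose and 1 fell of 18, 7 and 4 adjusted over the list alone, median -0.003 and camera direction up, adjusted p = 0.215), with Cd14 17.8-fold higher. The other lists that did not pass were corneal differentiation (camera adjusted p = 0.111), limbal and basal genes (0.0545), the endothelium (0.0559), nerve (0.0559), skeletal muscle (0.187), vessels (0.063), mitochondrially encoded genes (0.0559), interferons and receptors (0.434) and the conjunctiva (0.706, median -0.23 and camera direction up).

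Wounded corneas with and without RNase III shared 507 genes that were higher than in unwounded corneas, where independent lists would share 42.6, and 432 that were lower, against 66.4. Both comparisons use the same unwounded libraries, so a deviation of those libraries enters both. Simulated unchanged groups, which had almost no calls, shared 0 higher and 0.05 lower calls on average in 20 simulations and cannot size that part. The correlation of the fold changes was 0.836 (simulated 0.499), and the covariance 0.853 against 0.0792. Median-of-ratios scaling gave 1215 higher and 781 lower genes for RNase III against unwounded corneas, 60.9% higher in place of 50.8%, and moved the all-gene median from -0.162 to -0.009. Without unwounded replicate 1 these counts were 19 and 4, and without unwounded replicate 2 they were 14 and 3. Without RNase III replicate 1 they were 576 and 194, and without RNase III replicate 2 they were 306 and 444.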

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

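The comparisons rested on 2 samples per group and unknown depth. Counts of genes against unwounded corneas moved most without a filter, without some libraries and, for higher genes, with scaling. With the other choices they moved less, and few choices turned list directions. The cause was not tested unless named. Genes tested without a filter gave 179 higher and 265 lower for the wound and 44 and 25 for RNase III against unwounded corneas, with more low genes in the test. Median-of-ratios scaling gave 1544 higher for the wound and 1215 for RNase III against unwounded corneas. A pseudocount of 0.1 called 1 gene lower for RNase III against wounded corneas, where 0 was the main count. With an estimated correlation, where the test uses 3 residual degrees of freedom, 0 lists passed in each comparison. Leaving out 1 library, with fewer samples, gave 22 to 1297 higher and 3 to 1945 lower genes for the wound, 14 to 645 and 3 to 638 for RNase III against unwounded corneas, and 0 to 1 lower for RNase III against wounded corneas. The correlation of the wound and RNase III fold changes lay between -0.571 and -0.186. Over the named genes and passing lists, leaving out 1 library kept 891 results, weakened 474, strengthened 3 and reversed 12.

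Over all genes the replicate numbers gave little sign of pairing: deviations from group means correlated at 0.15, 0.10 and -0.05 between groups. Red blood cell and pigment and retina genes were higher in replicate 2 in all 3 groups. The replicate block gave 689 higher and 1343 lower genes for the wound, 605 and 844 for RNase III against unwounded corneas and 0 for RNase III against wounded corneas. With the replicate block 18, 17 and 14 lists passed in these comparisons in place of 15, 16 and 11. Added downward calls were pigment and retina (adjusted p = 0.0023), red blood cells (0.00163) and mitochondrial genes (0.0335) for the wound, mitochondrial genes (0.0343) against unwounded and red blood cells (3.89e-05) against wounded corneas. Lens and proliferation (0.0252 each) were added upward against wounded corneas.

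For the wound, Tlr3 turned from -0.17 to 0.091 with scaling and ranged from -0.52 to 0.19 without 1 library. For RNase III against wounded corneas, Tgfbi was -0.066 with scaling. Ranges without 1 library in this comparison were -2.1 to 1.01 for the neutrophil median, -1.11 to -0.03 for the cytokine median (whose test turned upward), -0.88 to 0.60 for Cxcl3, -0.92 to 0.18 for Gap43, -2.66 to 1.46 for S100a8, -2.78 to 1.64 for S100a9, -0.31 to 0.42 for Tgfbi and -0.60 to 0.26 for Tnni2.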

Other observations

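The genes in this paragraph were chosen only after their values were seen. Between RNase III and wounded corneas Trf, the gene of the iron carrier transferrin, had 238.12 and 255.46 TPM in wounded and 55.72 and 64.23 TPM in RNase III corneas (limma, adjusted p = 0.124). Ccl7, a monocyte chemokine, had 240.9 and 228.16 TPM against 24.19 and 41.05 TPM (log2 difference -2.86, SE 0.29, adjusted p = 0.16). Gpha2, a limbal stem cell gene, had 510.96 and 436.96 TPM against 108.93 and 150.6 TPM (adjusted p = 0.24). Of genes with higher values, Klk10, a kallikrein protease, had 25.87 and 35.21 TPM in wounded and 114.01 and 102.52 TPM in RNase III corneas, and the adhesion gene Ceacam1 213.55 and 184.67 TPM against 669.39 and 547.97 TPM (adjusted p = 0.24 for each). The glucose transporter gene Slc5a1 fell with the wound, from 90.69 and 87.06 TPM to 23.46 and 14.5 TPM, and had 69.33 and 65.17 TPM with RNase III. Lce3a, a cornified envelope gene, had 133.61 and 60.72 TPM in unwounded, 10.63 and 4.13 TPM in wounded and 122.85 and 61.2 TPM in RNase III corneas.

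Interferon-stimulated genes had lower values in wounded corneas with RNase III, and both tests of this pattern were chosen after the result was seen. The explanation that 1 RNase III library set the value fits, since the list median was 0.241 without RNase III replicate 1. With 2 RNase III libraries this is the value of replicate 2 alone, so it adds no support beyond the values by library. Per library the median difference from wounded corneas was -1.35 in RNase III replicate 1 and 0.241 in replicate 2. Replicate 1 also had 16751 genes above 0 TPM against 19455 in replicate 2. On the second principal component it stood at 64.34 against -5.02. Whether fewer macrophages in the sample could explain the lower interferon values cannot be told. The interferon list lay above the macrophage list by 0.425 in replicate 1 and 1.28 in replicate 2. An effect of RNase III or of its injection on the interferon response stays open and was not tested beyond these 2 libraries.

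Stroma and macrophage genes had lower values in wounded corneas with RNase III, and the tests here too were chosen after the result was seen. That 1 library set the value was tested on the keratocyte list. Its median was still -0.829 in the case nearest 0 without 1 library, which argues against that explanation. The fibrillar call held as well, though the size of its median moved with the RNase III library left out. The macrophage call also held, downward, without each library in turn. The macrophage median difference from wounded corneas was -1.77 in RNase III replicate 1 and -1.04 in replicate 2. Whether all tissue under the epithelium made up a smaller share stays open. The mean of the endothelium list (7 genes) lay above that of the keratocyte list (9 genes) by 1.29 (SE 0.412, from the spread between libraries). Of the endothelium genes 4 had higher and 3 lower values than in wounded corneas. As a list mean this goes against a smaller share. The nerve (median -0.61) and vessel (-0.55) lists were lower too, which goes with it, though leaving out 1 library brought these to -0.13 and -0.14. Col8a2 of the endothelium list had 53.75 and 105.24 TPM in wounded and 27.14 and 56.81 TPM in RNase III corneas. The pigment and retina (-1.26) and muscle (-1.48) lists were also lower, and -0.36 and -0.25 with 1 library left out. They stand for neighbouring tissue that can enter a corneal sample, so they cannot decide this question. Within unwounded corneas their summed TPM in replicates 1 and 2 were 1751.3 and 5620.3 for pigment and retina, and 160.7 and 13.4 for muscle. A deeper wound, the injection or RNase III itself may each lie behind the pattern, and none was tested.

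Lens crystallins were high in wounded replicate 2 and RNase III replicate 2, and the test was chosen after this was seen. Over 7 crystallins the ratio of RNase III replicate 2 to wounded replicate 2 had a median of 15.3 and a log2 SD of 0.594. Cryba4, with the lowest ratio of 9.13, had 37.46 and 37.15 TPM in wounded and RNase III replicate 1, no less than its 30.54 TPM in wounded replicate 2, so its value there need not come from lens. The other 6 crystallins had ratios from 14.6 to 32.1 and a log2 SD of 0.469. As these SDs lie on both sides of the bound of 0.5, the same mix of lens tissue in differing amounts stays open.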
